A study of Homo sapiens with 9 samples.

How the data were processed

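RNA from 9 samples of MCF10A cells, 3 unedited (Ctrl) and 3 of each BRCA2 mutation (del5 and delT), was sequenced by the authors after a stranded mRNA library preparation, per the labels' protocols, and each sample is 1 library. The deposited files hold raw counts per Ensembl gene and length- and depth-scaled transcript levels (TPM) for the same 57820 genes and 9 libraries, with no column left unused. The submitters' processing notes name the human genome build hg19, edgeR 3.38.2 and limma, without the role of each. The aligner, the counting program, its annotation, the strand it counted and the gene lengths behind the TPM values are not given in the sources used here. Gene names were available for 39538 genes and chromosomes for 52338, from GENCODE on a later genome build, of which only names, chromosome, gene order and GC content were used. Levels of genes that overlap another gene on either strand are uncertain for that reason.

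Groups were read from the sample titles before the data were examined, as were the 3 comparisons (del5 with Ctrl, delT with Ctrl, del5 with delT), the tests, 30 gene lists and the rule for naming genes. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, and the robust quasi-likelihood test in 1 model of all 9 libraries with no covariate. That left 16836 genes, 16302 of them placed on chromosomes 1 to 22 or X, and a Benjamini-Hochberg adjusted p under 0.05 counted as passing. Levels are TMM-scaled counts relative to library size (CPM), fold changes are log2, and the standard error is the fold change divided by the square root of the F statistic. A gene with 0 counts in a group is given as at least the fold from a floor of 3 counts per library, and a gene with 1 to 3 counts in a group as a ratio with a 95% counting interval. These bounds and intervals cover counting error only. The floor of 3 counts lay between 0.0328 and 0.0696 CPM.

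Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, for the 29 lists meant for testing with at least 5 measured members, adjusted over the lists of a comparison. The list of genes that check the cell line is given as values. Each list is also given as the number of members that passed over all genes and the number that passed when adjusted over the list alone. The same test was run on 23 chromosomes with at least 50 tested genes each. Named genes are those that passed, did not overlap between groups, had a mean of at least 5 CPM in the higher group and an approved protein-coding symbol, taking the 10 largest increases and 10 largest decreases per comparison (5 and 5 for del5 with delT), up to 4 members per list with the smallest adjusted p, and BRCA2. Any other gene is said to be chosen after its values were seen. Some genes that meet the rule are not reported here. Exact permutation tests ran over all 84 splits of 9 libraries into 3 and 6.

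Other settings fixed beforehand were DESeq2 1.42.0, DESeq2 size factors, library size alone, no expression filter, at least 1 CPM in 3 libraries, limma-voom, a fit of the 2 groups alone, the replicate number as a block, the identifier prefix as a model term, and limma-trend on deposited TPM with a pseudocount of 1 or 0.1 (TPM of at least 1 in 3 libraries) and with no filter. They also included an inter-gene correlation estimated by camera, a 2-fold threshold, and each of the 9 libraries left out. Chosen after the data were seen were fits with chromosome medians removed, with a trend on GC content removed (GC known for 97.0% of tested genes), with delT 2 and delT 3 summed, of the libraries of each shared identifier prefix alone, and without Ctrl 1 and del5 2 together. With the prefix as a term, a library that has a prefix of its own adds nothing to the test, which is then weaker. In a fit of 1 prefix alone the single library of a group is taken to vary like the other group. For delT 2 and delT 3, the closest pair, this makes p-values of genes too small. The test was checked on simulated counts with 100 genes changed 2-fold or 4-fold: it called 21, 26 and 16% of 2-fold and 66, 65 and 66% of 4-fold genes in del5 with Ctrl, delT with Ctrl and del5 with delT, with 7, 1 and 3 false calls. A simulated 1.5-fold rise of chromosome 20 came back as a median of 0.59, with 0 of the other 22 chromosomes called. These simulations drew each gene independently and gave all groups the same spread. They therefore do not show how often the preset correlation calls chromosomes or lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Alleles, splicing and variants in reads were not analysed here, since the files hold gene totals.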

Results

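Messenger RNA was sequenced from MCF10A, a non-malignant human breast epithelial cell line, in 9 libraries that form 3 groups of 3. Ctrl libraries came from clones of unedited parental cells. The del5 and delT libraries came from cells edited with CRISPR/Cas9 or TALEN nucleases. They carry a truncating mutation of BRCA2, a 5-base deletion named del5 and a deletion of a single T named delT. BRCA2 acts in the repair of broken DNA by homologous recombination. The comparisons ask what each truncating mutation changes in the cells' transcripts and whether the 2 mutations change them alike. Total counts, rounded to 6 digits, were 91499600, 69263000 and 83167600 in Ctrl 1 to 3. They were 56081100, 50071500 and 89459900 in del5 1 to 3, and 50061500, 46809100 and 43132100 in delT 1 to 3. The labels do not say whether the 3 libraries of a group came from separate clones, cultures or RNA preparations. All p-values below therefore measure only the spread between these libraries, which may be technical.

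The mitochondrial cytochrome oxidase gene MT-CO1 was the most abundant transcript of every library, at 1.62 to 2.52% of counts, and mitochondrially encoded genes together took 5.74 to 9.68%. Between 22104 and 25458 genes had at least 1 count. The first principal component of log2 counts scaled to library size (CPM) held 49.1% of the variance. It placed the 3 delT libraries (84.6, 93.8 and 94.7) apart from the other 6 (-75.4 to -22.6). Spread within a group, as the biological coefficient of variation, was 40.1% in Ctrl, 35.5% in del5 and 21.2% in delT. The libraries delT 2 and delT 3 were much closer to each other than any other pair of the same group. Their counts differed by a chi-square per degree of freedom of 10.3, against 98.3 to 583 in the other 8 pairs. Ctrl 3, delT 2 and delT 3 shared a prefix in their sample identifiers, as did del5 1, del5 2 and delT 1. The remaining 3 libraries had a prefix each. What the prefix stands for is not given in the sources used here.

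BRCA2 (ENSG00000139618, chromosome 13) was transcribed in every library and stood higher in the 3 delT libraries than in the other 6. Its level was 15.3, 11.2 and 14.8 CPM in Ctrl 1 to 3 (13.8 ± 2.23, SD, n = 3). It was 14.95, 7.79 and 16.5 CPM in del5 1 to 3 (13.1 ± 4.65) and 26.8, 24.8 and 20.7 CPM in delT 1 to 3 (24.1 ± 3.10). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes, del5 differed from Ctrl by a log2 fold change of -0.07 (SE 0.27, adjusted p = 0.986). For delT against Ctrl it was 0.81 (SE 0.28, adjusted p = 0.0900) and for del5 against delT -0.88 (SE 0.28, adjusted p = 0.0699). None of these passed an adjusted p of 0.05. With 1 library left out the del5 difference ranged from -0.27 to 0.19, and it turned to 0.01 without Ctrl 1 and to 0.19 without del5 2. With the identifier prefix as a term it was -0.61, in a fit where no prefix holds both a del5 and a Ctrl library. The delT difference passed without del5 2 (0.82, adjusted p = 0.0200), with DESeq2 (0.81, adjusted p = 0.0300) and with the Ctrl and delT libraries fitted alone (0.80, adjusted p = 0.0404). The difference between del5 and delT passed with DESeq2 (-0.89, adjusted p = 0.0162) and with replicate numbers as a block (-0.94, adjusted p = 0.0489). In delT 2 and 3 against Ctrl 3, which share an identifier prefix, it was 0.61, a value with no error of its own for the lone Ctrl library. With each library's chromosome medians taken out, the delT difference was 0.31 (adjusted p = 0.525). Gene counts do not separate the edited from the unedited allele.

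**Figure D1:**
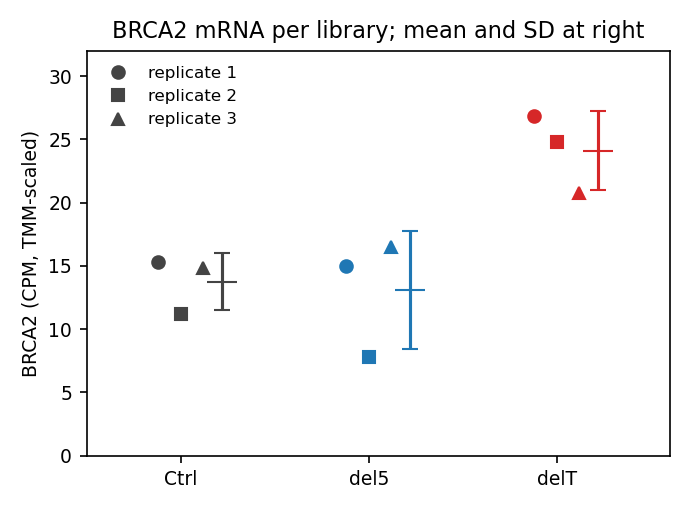
BRCA2 level in TMM-scaled CPM (vertical axis) for each of the 9 libraries (points, shaped by replicate number) by group (horizontal axis), with the group mean (horizontal bar) and SD (error bars, n = 3 libraries) to the right of the points. The 3 delT libraries lie between 20.7 and 26.8 CPM and the other 6 between 7.79 and 16.5 CPM.

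Genes that check the identity of the line were read in every library. CDKN2A and CDKN2B, inhibitors of G1 cyclin-dependent kinases that MCF10A is known to have lost, had at most 3 counts and 0 counts per library. Their neighbour MTAP had at most 11. MYC, a growth-promoting transcription factor that is amplified in the line, was abundant in every library, from 219 to 720 CPM.

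Cells with the delT mutation differed from Ctrl in many genes, some of which went from silence to moderate expression or the reverse. SLAIN1, a regulator of microtubule growth, reached 9.80 ± 2.98 CPM in delT (SD, n = 3) and had 0 counts in all 3 Ctrl libraries, at least 263-fold higher at a floor of 3 counts per library. NELL2, a secreted axon guidance factor, was 2371-fold higher (95% counting interval 656 to 19590). MYH14, a non-muscle myosin, was 966-fold higher (330 to 4691) and KANK4 682-fold (233 to 3311). PDE3B, a cyclic nucleotide phosphodiesterase, rose by a log2 fold change of 7.52 (SE 0.76, adjusted p = 0.000930). The cell adhesion receptor TENM1 rose by 7.39 (SE 0.59, adjusted p = 0.000541) and the transporter SLC47A1 by 7.36 (SE 0.98, adjusted p = 0.00284). ZNF711 rose by 8.08 and ENPP4 by 7.67, with all of their 13 and 8 Ctrl counts in Ctrl 2. Without Ctrl 2 they were at least 451-fold and at least 211-fold higher in delT, at the same floor. In the other direction CNTN3, a neural adhesion molecule, was 2191-fold lower in delT (95% counting interval 393 to 86555). The lipid kinase PIK3C2G was 856-fold lower (153 to 33824), TDRD5 528-fold (146 to 4366) and the zinc finger gene ZNF22 434-fold (148.5 to 2108). The transcription factor ATOH8 was 763-fold lower (261 to 3701), with Ctrl libraries far apart (16.6 ± 22.2 CPM). The calls of the other 5 of the 10 largest decreases ended in some fits with 1 library left out. In no such fit did their log2 fold change move by over 1.5 times. PTGFR (at least 126-fold) ended without delT 2 (adjusted p = 0.0533) or delT 3 (0.0521) and CADM3 without delT 2 (0.0530). ACKR1 (at least 102-fold) and MYBPC1 ended without any 1 delT library (0.0748 to 0.0871). NLGN4X ended without Ctrl 1 (0.0515) or any 1 delT library (0.0933 to 0.110).

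Of 16836 genes tested with edgeR, 2077 (12.3%) passed an adjusted p of 0.05 between delT and Ctrl, 939 higher and 1138 lower in delT. Of these 1388 also changed at least 2-fold. Replicate values of the 2 groups did not overlap for 5891 genes (35.0%, where chance gives 10%). The count was 1269 without delT 1, 641 without delT 2 and 724 without delT 3. With delT 2 and delT 3 summed into 1 library it was 742, 732 of them among the 2077. With the identifier prefix as a term of the model, which leaves delT 2 and 3 against Ctrl 3 as the only direct comparison, 46 genes passed. That fit has few libraries left to estimate the spread, so the fall to 46 does not show that the prefix accounts for the calls. All 97 named genes kept their sign, but they were chosen in these same libraries, so this is no separate support. Of the 97 genes chosen by rule that passed, 48 passed in every fit with 1 library left out. Genes named for this comparison are among those 48 unless a library is given beside them.

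Genes on 5 chromosomes stood higher in delT than in Ctrl as whole sets. The median log2 fold change was 0.46 on chromosome 7 (809 genes), 0.34 on chromosome 8 (605 genes) and 0.47 on chromosome 13 (284 genes). It was 0.62 on chromosome 19 (1082 genes) and 0.45 on chromosome 20 (426 genes). PMEPA1, a TGF-beta feedback inhibitor on chromosome 20, rose from 19.4 ± 1.94 to 106 ± 3.00 CPM. ESRP1, an epithelial splicing regulator on chromosome 8, rose from 121 ± 15.1 to 214 ± 33.6 CPM. Within single libraries, the median of these 5 chromosomes stood 0.56, 0.62 and 0.62 log2 units above that of the other chromosomes in delT 1, 2 and 3. This is 1.48-, 1.54- and 1.53-fold. In the other 6 libraries this difference lay between -0.10 and 0.08. The means were 0.60 ± 0.03 (SD, n = 3) in delT and 0.03 ± 0.07 (n = 6) in the others. The genes higher in delT were concentrated there. On the 5 chromosomes, which hold 19.7% of the placed genes, lay 663 of 939 higher genes (71.5% of those placed on a chromosome). Of 1138 lower genes 88 did (7.83%). These shares carry no test, since the 5 chromosomes were chosen after their values were seen.

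By limma's camera with a preset inter-gene correlation, 10 of 23 chromosomes passed between delT and Ctrl. The 5 above were higher (adjusted p = 3.38e-12, 2.83e-07, 2.09e-10, 4.76e-19 and 1.13e-11 in that order). Chromosomes 3, 4, 6, 10 and X were lower, by medians of -0.14, -0.15, -0.13, -0.13 and -0.18. Every chromosome outside the higher 5 had a median below 0, from -0.18 (X) to -0.03 (chromosome 11). Levels are relative within a library, so a fall of these chromosomes cannot be told from the rise of the others. None of the 5 lower ones passed with an estimated correlation (camera adjusted p 0.0857 to 0.189). With an estimated correlation chromosomes 7, 8, 13 and 20 passed (adjusted p = 1.51e-05, 0.00136, 0.0335 and 0.0192). Chromosome 1 also passed (median -0.11, adjusted p = 0.0335), and chromosome 19 did not (adjusted p = 0.0942). The higher 5 passed in each fit with 1 library left out, whereas the number of chromosomes fell to 6 without Ctrl 1. When each chromosome was divided into 10 equal segments of genes in order, 47 of the 50 segments of the 5 chromosomes had a median above 0.25. These were all segments of chromosomes 7, 13, 19 and 20 and 7 of 10 of chromosome 8. Elsewhere 0 of 180 segments did and 13 lay below -0.25.

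**Figure D2:**
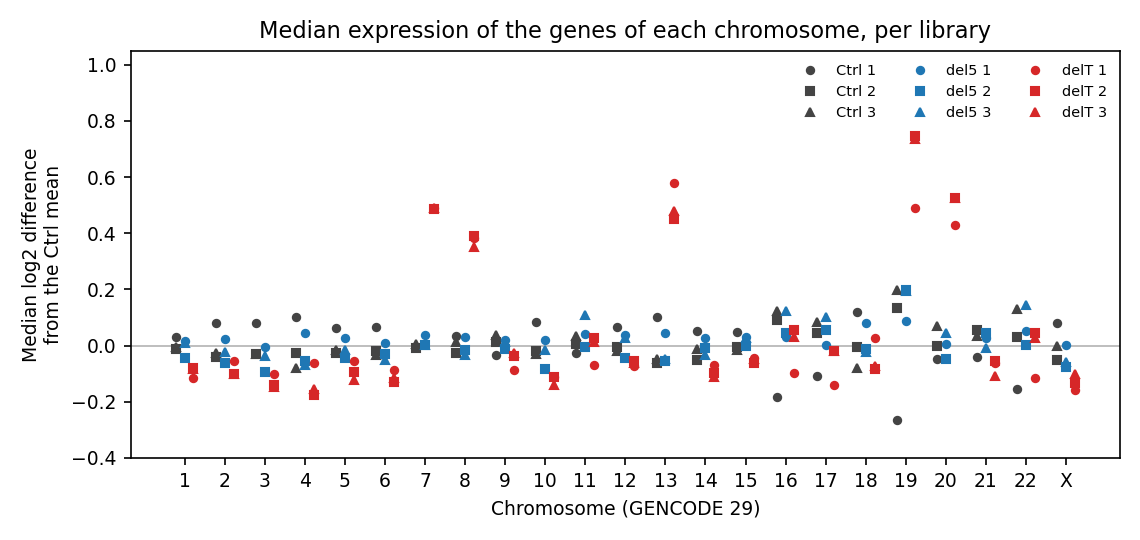
Median over each chromosome's genes of the log2 difference from the Ctrl mean (vertical axis) by chromosome (horizontal axis), with 1 point per library, coloured by group and shaped by replicate number. The delT libraries lie between 0.35 and 0.75 on chromosomes 7, 8, 13, 19 and 20, above every Ctrl and del5 library.

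**Figure D3:**
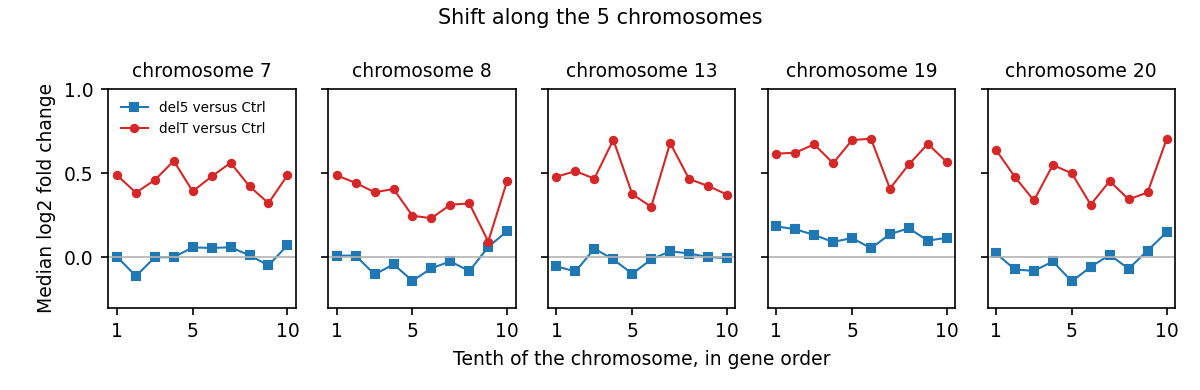
Median log2 fold change of delT against Ctrl and of del5 against Ctrl (vertical axis) in each of 10 segments of a chromosome's genes in order (horizontal axis), with 1 panel for each of the 5 chromosomes. In delT, 47 of 50 segments lie above 0.25, and in del5 0 of 50 do.

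Inflammatory and interferon-induced genes were lower in delT than in Ctrl. The neutrophil chemoattractant CXCL8 fell by a log2 fold change of 5.48 (SE 0.50, adjusted p = 0.000625), from 80.9 ± 32.2 to 1.80 ± 0.704 CPM. Its relatives CXCL1 and CXCL3 changed by -4.52 (SE 0.48, adjusted p = 0.00113) and -3.38 (SE 0.37, adjusted p = 0.00126), with reads that near-identical members of the family may share. IRAK2, a kinase of interleukin-1 signalling, changed by -2.58 (SE 0.39, adjusted p = 0.00469). Among interferon-stimulated genes BST2, which tethers budding virus, changed by -6.82 (SE 0.97, adjusted p = 0.00388) and IFI44L by -5.32 (SE 0.68, adjusted p = 0.00233). IFI44 changed by -3.32 (SE 0.53, adjusted p = 0.00615) and the ISG15 ligase HERC5 by -2.81 (SE 0.48, adjusted p = 0.00774). Of 28 NF-kB targets and cytokines 10 fell and 1 rose (11 and 1 adjusted over the list alone). The list median was -1.26 (camera adjusted p = 0.00146, and adjusted p = 0.492 with an estimated correlation), or -0.70 with the identifier prefix as a term. Of 41 interferon-stimulated genes 10 fell (11 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.00102, and adjusted p = 0.578 with an estimated correlation). The lower NF-kB members numbered 6 without delT 2 and 6 without delT 3. The lower interferon genes numbered 6 without Ctrl 3, 5 without delT 1, 4 without delT 2 and 5 without delT 3. The 1 NF-kB member that rose was the granulocyte growth factor CSF3 (2.06, SE 0.49, adjusted p = 0.0263), chosen after its values were seen. Its call ended without any 1 Ctrl or delT library (adjusted p 0.05001 to 0.0987), and 2 members rose without del5 2.

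Antigen presentation genes fell by a list median of 0.74 log2 units in delT (18 members, camera adjusted p = 0.00314, and adjusted p = 0.618 with an estimated correlation). Over all genes 3 members passed, and 8 adjusted over the list alone. They included the class I light chain B2M (-0.99, SE 0.22, adjusted p = 0.0221) and the peptide-trimming enzyme ERAP1 (-0.88, SE 0.24, adjusted p = 0.0429). None of the 3 passed in every fit. B2M ended without Ctrl 1, delT 2 or delT 3 (adjusted p 0.0539 to 0.0994). ERAP1 ended without any 1 library other than del5 1 or del5 2 (0.0519 to 0.139). The members passing over all genes were 2 without Ctrl 2, Ctrl 3 or del5 3, 1 without delT 1 and 0 without delT 2 or delT 3. Without Ctrl 3 the list median was -0.58 (adjusted p = 0.05001, above the threshold).

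Genes of the NRF2 pathway, which guards cells against oxidants and electrophiles, were lower in delT. The efflux pump ABCC2 changed by a log2 fold change of -4.43 (SE 0.39, adjusted p = 0.000559), from 177 ± 58.1 to 8.19 ± 1.22 CPM. The aldo-keto reductase AKR1B10 changed by -6.00 (SE 0.78, adjusted p = 0.00267) and the glutathione transferase MGST1 by -1.12 (SE 0.14, adjusted p = 0.00217). AKR1C3 changed by -4.85 (SE 0.67, adjusted p = 0.00334), with reads that AKR1C1 and AKR1C2 may share. Of 28 measured members 13 fell and none rose (16 adjusted over the list alone). The list median was -1.13 (camera adjusted p = 1.49e-07, and adjusted p = 0.479 with an estimated correlation). The count was 7 without delT 1, 6 without delT 2 and 7 without delT 3. The median was -0.42 (adjusted p = 0.00288) with the identifier prefix as a term. Of 12 aldehyde-detoxifying enzymes 2 fell (3 adjusted over the list alone; list adjusted p = 0.186). They were ALDH3A2, by -1.08 (SE 0.18, adjusted p = 0.00687), and ALDH3A1, by -3.21 (SE 0.60, adjusted p = 0.0104, and 0.0514 without delT 2). The number lower was 1 without delT 2, and 1 member was higher without Ctrl 1 or del5 2.

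Cholesterol synthesis genes had a median of -0.57 in delT (24 members, camera adjusted p = 0.00465, and adjusted p = 0.618 with an estimated correlation). Over all genes and over the list alone 4 members passed. They included the cyclase LSS (-0.89, SE 0.23, adjusted p = 0.0341) and the decarboxylase MVD (-0.89, SE 0.23, adjusted p = 0.0377). Each call ended in 6 or more of the fits with 1 library left out. LSS and MVD ended without Ctrl 2, Ctrl 3, del5 3 or any 1 delT library (adjusted p 0.0522 to 0.112). No member passed without Ctrl 2, del5 3 or any 1 delT library, and 6 passed without Ctrl 3 or del5 2. With the identifier prefix as a model term the list median was -0.11 (adjusted p = 0.649). In delT 2 and 3 against Ctrl 3 alone it was -0.12 (adjusted p = 0.219).

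Matrix genes were lower in delT as a set, as were most of the mesenchymal genes that passed. THBS1, a matrix glycoprotein that activates TGF-beta, changed by -2.67 (SE 0.22, adjusted p = 0.000559). The collagen COL8A1 changed by -5.66 (SE 0.73, adjusted p = 0.00248), the collagen COL4A5 by -0.81 (SE 0.13, adjusted p = 0.00638) and the fibulin-like EFEMP1 by -1.36 (SE 0.22, adjusted p = 0.00622). Of 35 matrix genes 10 fell and 1 rose (13 and 2 adjusted over the list alone). The list median was -0.42 (camera adjusted p = 0.0195, and adjusted p = 0.410 with an estimated correlation). The 1 that rose, the laminin chain LAMA1 (1.10, SE 0.21, adjusted p = 0.0117), was chosen after its values were seen and did not pass without delT 2 (adjusted p = 0.0618) or delT 3 (0.0551). The matrix list did not pass without Ctrl 2 (-0.50, adjusted p = 0.0554) or in delT 2 and 3 against Ctrl 3 alone (-0.63, adjusted p = 0.0761). Its higher members numbered 2 without Ctrl 2 and 0 without delT 2 or delT 3, and its lower members 6 without delT 1 and 4 without delT 2 or delT 3. Of 33 mesenchymal genes 10 fell and 1 rose (11 and 2 adjusted over the list alone). Those that fell included N-cadherin, CDH2 (-2.45, SE 0.41, adjusted p = 0.00747). The 1 that rose was MYL9, a myosin light chain on chromosome 20 (2.86, SE 0.48, adjusted p = 0.00720). The mesenchymal list did not pass (median -0.33, adjusted p = 0.0526). Without delT 1, delT 2 and delT 3 its lower members numbered 5, 3 and 3, with 2 higher without Ctrl 2 or Ctrl 3.

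Of 10 markers of stromal cells, fixed to look for other cell types, 5 fell in delT. TEK, an endothelial receptor, changed by -4.29 (SE 0.54, adjusted p = 0.00217), from 1.73 ± 0.470 to 0.0879 ± 0.0651 CPM. The small proteoglycan DCN changed by -5.28 (SE 1.00, adjusted p = 0.0112, and 0.0534 without delT 3). The fibulin FBLN1, also a matrix gene, changed by -1.92 (SE 0.36, adjusted p = 0.0108, and 0.0517 without delT 2 and 0.0506 without delT 3). KDR (-1.90, adjusted p = 0.0411) and PDPN (-1.97, adjusted p = 0.0476, chosen after its values were seen) completed the 5 that passed, in all genes and over the list alone. KDR ended without any 1 library other than del5 1 or del5 2 (0.0571 to 0.153) and PDPN without any 1 library (0.0510 to 0.116). The list median was -1.10 (camera adjusted p = 0.0298, and adjusted p = 0.479 with an estimated correlation). It did not pass without Ctrl 2 (-1.66, adjusted p = 0.0554), Ctrl 3 (-1.63, 0.109), del5 1 (-1.10, 0.0659), del5 2 (-0.30, 0.0716) or delT 1 (-1.24, 0.225). It moved to -1.90 without del5 3 and -1.85 without delT 2. With no expression filter it was -0.17 (adjusted p = 0.665), and with replicate numbers as a block -1.07 (adjusted p = 0.0612). Lower members numbered 3 without Ctrl 1, Ctrl 2, Ctrl 3, del5 3 or delT 1, 2 without delT 2 and 1 without delT 3, and 1 member was higher without delT 1. Of 6 immune cell markers 1 fell (also over the list alone; list adjusted p = 0.344). It was the macrophage receptor CSF1R (-1.78, SE 0.35, adjusted p = 0.0132), which ended without delT 2 (0.0523) or delT 3 (0.0654).

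Epithelial genes moved in both directions in delT. The tight junction protein CLDN1 changed by -1.78 (SE 0.24, adjusted p = 0.00298). The desmosomal plakophilin PKP2 changed by -1.49 (SE 0.15, adjusted p = 0.000969) and the epidermal transcription factor GRHL3 by -1.49 (SE 0.24, adjusted p = 0.00583). ESRP1 rose by 0.82 (SE 0.16, adjusted p = 0.0121). CLDN7 (1.11, SE 0.27, adjusted p = 0.0271) and OVOL1, a repressor of mesenchymal genes (80 counts against 3), also rose and were chosen after their values were seen. In all 3 of 36 junction genes rose and 3 fell, in all genes and over the list alone (list adjusted p = 0.0908). CLDN7 ended without Ctrl 2, Ctrl 3 or any 1 delT library (0.0612 to 0.0910) and OVOL1 without delT 2 (0.0622) or delT 3 (0.0586), which left 1 higher gene. Of 18 luminal genes 4 fell, in all genes and over the list alone (list adjusted p = 0.142). They were the simple keratins KRT8 (-1.72, SE 0.29, adjusted p = 0.00764) and KRT18 (-0.92, SE 0.18, adjusted p = 0.0122), the disulfide isomerase AGR2 (-3.86, SE 0.66, adjusted p = 0.00764) and the luminal transcription factor GATA3 (-1.053, SE 0.30, adjusted p = 0.0484). KRT18 ended without delT 2 (0.0587) or delT 3 (0.0642) and GATA3 without any 1 library other than Ctrl 1 (0.0537 to 0.139). Lower members numbered 2 without delT 2 or delT 3, and 1 was higher without Ctrl 2 or del5 2. Of 28 basal genes 1 rose and 1 fell (0 and 0 over the list alone; list adjusted p = 0.476). They were EGFR on chromosome 7 (0.52, SE 0.15, adjusted p = 0.0473) and the basal keratin KRT14 (-4.46, SE 1.18, adjusted p = 0.0385). EGFR ended without any 1 library other than del5 2 (0.0572 to 0.178) and KRT14 without Ctrl 3, del5 3 or any 1 delT library (0.0572 to 0.130, and -2.56 without Ctrl 3). Lower basal genes numbered 2 without del5 1 and 3 without del5 2.

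Epidermal differentiation genes rose in delT by a list median of 0.80 (30 members, camera adjusted p = 0.00520, and adjusted p = 0.410 with an estimated correlation). KRT13, a keratin of stratified mucosa, reached 36.1 ± 10.99 CPM against 0.277 ± 0.113 in Ctrl (7.001, SE 0.94, adjusted p = 0.00292). The kallikrein proteases KLK10 and KLK8, on chromosome 19, were 1503-fold (95% counting interval 514 to 7293) and 132-fold (35.8 to 1096) higher. The type II keratin KRT80 was lower (-2.82, SE 0.46, adjusted p = 0.00639), as were the calprotectin subunits S100A8 (-5.42) and S100A9 (-4.09), chosen after their values were seen. In all 9 members rose and 3 fell (11 and 4 adjusted over the list alone), and 7 of the 9 lie on the 5 higher chromosomes. The list median was 1.30 without Ctrl 2, 1.40 without Ctrl 3, 1.34 without delT 1 and 0.39 without delT 3. It was 0.38 (adjusted p = 0.114) when genes needed at least 1 CPM in 3 libraries and 1.64 in delT 2 and 3 against Ctrl 3 alone. Higher members numbered 15 without del5 2 and 5 without delT 2 or delT 3, and lower members 2 without Ctrl 3 and 1 without any 1 delT library. S100A8 did not pass without any 1 delT library (0.0642 to 0.0812), nor S100A9 without Ctrl 3 (0.0531) or any 1 delT library (0.0770 to 0.0993).

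Lists of genome maintenance and cell division were higher in delT as sets with the preset correlation, with few single genes past the test. Homologous recombination and Fanconi anaemia genes had a median of 0.37 (44 members, camera adjusted p = 0.00102, and adjusted p = 0.618 with an estimated correlation). Mitosis genes had a median of 0.46 (49 members, adjusted p = 0.000504, and adjusted p = 0.667 with an estimated correlation). Replication genes had 0.30 (50 members, adjusted p = 0.00520, and adjusted p = 0.725 with an estimated correlation). R-loop processing genes had 0.21 (22 members, adjusted p = 0.0291, and adjusted p = 0.618 with an estimated correlation). Without Ctrl 1 the first 3 medians were 0.60, 0.71 and 0.46. Replication did not pass without Ctrl 2 (0.15, adjusted p = 0.241). R-loop genes did not pass without Ctrl 2 (0.16, adjusted p = 0.0711) or without Ctrl 3 (0.20, adjusted p = 0.05001, above the threshold). Nor did they with chromosome medians taken out (0.19, adjusted p = 0.0532), with the identifier prefix as a term (0.13, adjusted p = 0.0798) or in delT 2 and 3 against Ctrl 3 alone (0.12, adjusted p = 0.0505).

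The single genes of these lists that passed in delT were all higher. In the recombination list they were the DNA break sensor NBN on chromosome 8 (0.54, SE 0.11, adjusted p = 0.0175) and the meiotic recombinase DMC1 (2.21, SE 0.45, adjusted p = 0.0145). In the replication list they were the helicase subunit MCM7 (1.04, SE 0.26, adjusted p = 0.0306) and the ligase LIG1 (0.97, SE 0.22, adjusted p = 0.0205). In the mitosis list they were the anaphase ubiquitin carrier UBE2C (1.54, SE 0.30, adjusted p = 0.0131) and the spindle factor TPX2 (1.13, SE 0.29, adjusted p = 0.0323). In the R-loop list they were the exonuclease XRN2 (0.67, SE 0.13, adjusted p = 0.0119) and the ribonuclease H2 subunits RNASEH2A (1.29, SE 0.29, adjusted p = 0.0205) and RNASEH2B (0.84, SE 0.17, adjusted p = 0.0143). Except DMC1 all of these lie on chromosomes 7, 8, 13, 19 or 20. Adjusted over the list alone the counts were 2 of recombination, 0 of replication, 1 of mitosis and 3 of R-loop genes. UBE2C ended without delT 2 (0.0572) and XRN2 without delT 2 (0.0501). DMC1 ended without delT 2 (0.0559) or delT 3 (0.0831), and NBN without any 1 delT library (0.0501 to 0.0851). RNASEH2B ended without delT 1 (0.0505) or delT 2 (0.0610). LIG1 ended without Ctrl 2 (0.0582), delT 2 (0.0909) or delT 3 (0.0804). RNASEH2A ended without Ctrl 2 (0.0558), Ctrl 3 (0.0513), delT 2 (0.0784) or delT 3 (0.0746). MCM7 and TPX2 ended without Ctrl 2, Ctrl 3 or any 1 delT library (0.0564 to 0.109). Recombination counted 4 higher genes without Ctrl 1, 6 without del5 2, 1 without delT 1 and 0 without delT 2 or delT 3. Replication counted 4 without Ctrl 1 or del5 2, 1 without Ctrl 3 or delT 1, and 0 without Ctrl 2, delT 2 or delT 3. Mitosis counted 9 without del5 2, 1 without Ctrl 2, Ctrl 3, delT 1 or delT 3, and 0 without delT 2. R-loop processing counted 2 without Ctrl 2, Ctrl 3, delT 1 or delT 3 and 0 without delT 2.

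Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, fell by a list median of 1.64 log2 units in delT (12 members, camera adjusted p = 0.0148, and adjusted p = 0.618 with an estimated correlation). Over all genes 2 of 12 passed, and 5 adjusted over the list alone. The 2 were the linker histone H1-2 (-2.74, SE 0.68, adjusted p = 0.0307) and H2BC12 (-1.93, SE 0.48, adjusted p = 0.0307), with reads that near-identical histone genes may share. The list did not pass without Ctrl 3 (-0.77, adjusted p = 0.0841) or delT 1 (-1.43, adjusted p = 0.0504). H1-2 ended without Ctrl 3 or any 1 delT library (0.0708 to 0.112) and moved to -1.71 without Ctrl 3. H2BC12 ended without del5 3 or any 1 delT library (0.0503 to 0.0998) and moved to -1.13 without Ctrl 3. Of all 12 members 1 passed without Ctrl 3 or del5 3, 3 without del5 2 and 0 without any 1 delT library.

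Targets of p53, TGF-beta, ERK and YAP/TAZ, and genes of glycolysis, oxidative phosphorylation and stress responses, did not pass as sets between delT and Ctrl, while single members did. Of 34 p53 targets 4 fell and 1 rose, in all genes and over the list alone (adjusted p = 0.561), with the polo-like kinase PLK2 at -1.24 (SE 0.21, adjusted p = 0.00755). Of 26 TGF-beta targets 2 rose and 2 fell (3 and 2 over the list alone; adjusted p = 0.226), with PMEPA1 at 2.45 (SE 0.17, adjusted p = 0.000241). Of 30 ERK-responsive genes 2 fell (1 over the list alone; adjusted p = 0.885), with the ERK phosphatase DUSP5 at -1.94 (SE 0.27, adjusted p = 0.00325). Of 36 glycolysis and hypoxia genes 5 fell (6 lower and 1 higher over the list alone; adjusted p = 0.0947), with the mitophagy receptor BNIP3L at -1.27 (SE 0.22, adjusted p = 0.00747). Of 22 YAP/TAZ targets 3 fell (5 lower and 1 higher over the list alone; adjusted p = 0.0908). Of 30 stress response genes 1 rose (0 over the list alone; adjusted p = 0.556). Of 46 nuclear oxidative phosphorylation subunits 1 rose (0 over the list alone; adjusted p = 0.758). Of 11 stress and RNA handling genes 1 fell (1 lower and 1 higher over the list alone; adjusted p = 0.712). None of 13 mitochondrial messenger RNAs (adjusted p = 0.344) or 52 ribosomal protein genes (adjusted p = 0.773) passed, over all genes or over the list alone. For ribosomal and ERK-responsive genes the list median and mean differed in sign (-0.06 and 0.03, and 0.05 and -0.06).

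Counts of these lists moved with single libraries. Without delT 2 or delT 3 the lower p53 targets numbered 1, the lower glycolysis genes 1, the lower YAP/TAZ and TGF-beta targets 0 and the higher TGF-beta targets 1. Without delT 1 these were 2, 2, 1, 0 and 1. Without Ctrl 3 no YAP/TAZ target was lower and no p53 target higher. Without del5 2 there were 2 higher p53 targets, 3 higher stress response genes and 2 higher oxidative phosphorylation genes.

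Most other members of these lists that passed lost their call in some fits with 1 library left out, while each kept its direction. SESN1 (-0.95, adjusted p = 0.0108) ended without delT 2 (0.0533) or delT 3 (0.0570) and BNIP3 (-0.77, adjusted p = 0.0159) without delT 2 (0.0760) or delT 3 (0.0696). TGIF1 (-0.71, adjusted p = 0.0192) and ENO1 (-0.81, adjusted p = 0.0206) ended without any 1 delT library (0.0577 to 0.0936). ZMAT3 (-0.72, adjusted p = 0.0257), the stress cytokine GDF15 (1.87, adjusted p = 0.0322), the connective tissue growth factor CCN2 (-2.03, adjusted p = 0.0246) and the nuclear RNA NEAT1 (-1.80, adjusted p = 0.0222) ended without Ctrl 3 or any 1 delT library (0.0539 to 0.103). ADM (-1.52, adjusted p = 0.0221) ended without Ctrl 1 or any 1 delT library (0.0543 to 0.0994). RBMS3 (-0.94, adjusted p = 0.0284) ended without Ctrl 2, Ctrl 3 or any 1 delT library (0.0577 to 0.113). SPRY4 (-1.13, adjusted p = 0.0346) ended without del5 3 or any 1 delT library (0.0563 to 0.136, and -0.69 without Ctrl 3). ID1 (1.75, adjusted p = 0.0466) ended without any 1 library other than Ctrl 3, del5 1 or del5 2 (0.0686 to 0.128). CRIM1 (-0.64, adjusted p = 0.0437) ended without any 1 library other than Ctrl 2 or del5 2 (0.0582 to 0.148) and NDUFB9 (0.47, adjusted p = 0.0417) without any 1 other than del5 2 (0.0562 to 0.165). The asparagine synthetase ASNS (2.29, adjusted p = 0.0419) ended without any 1 library other than del5 1, del5 2 or delT 2 (0.0582 to 0.104), and was 1.14 without delT 1. TP53I3 (-1.42, adjusted p = 0.0405) and LDHA (-0.71, adjusted p = 0.0311), both chosen after their values were seen, ended in 7 and 6 of 9 fits (0.0502 to 0.123). The exceptions were Ctrl 2 and del5 2 for both and del5 1 for LDHA.

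**Figure D4:**
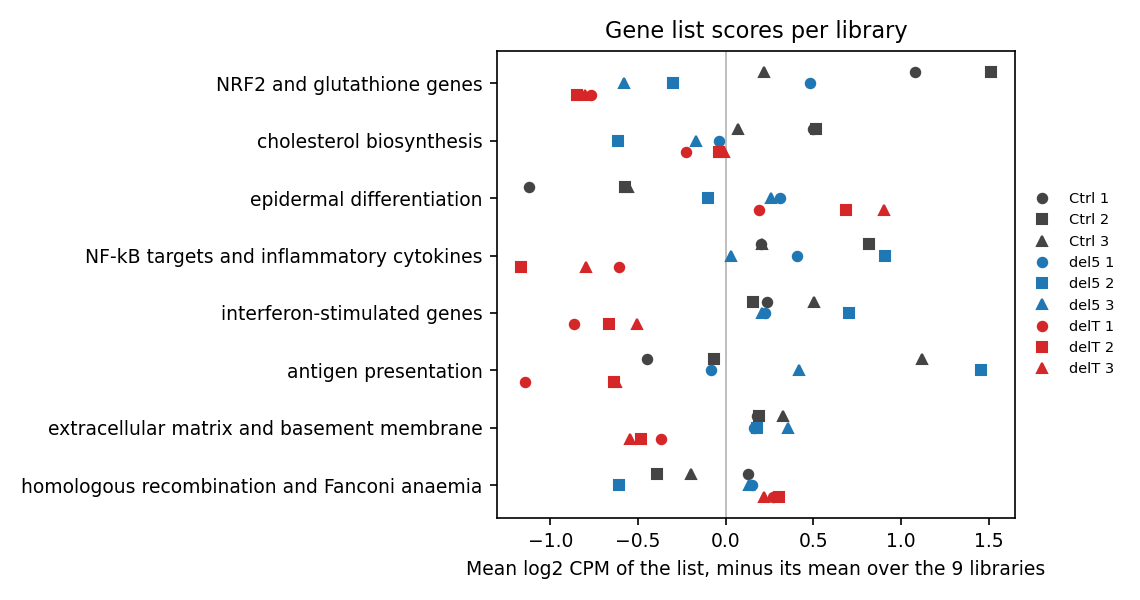
Score of 8 gene lists (vertical axis) in each of the 9 libraries, as the mean log2 CPM of a list's genes minus its mean over the 9 libraries (horizontal axis), with 1 point per library, coloured by group and shaped by replicate number. NRF2 genes lie at 1.08, 1.51 and 0.22 in Ctrl 1 to 3, 0.48, -0.30 and -0.58 in del5 1 to 3 and -0.77, -0.85 and -0.80 in delT 1 to 3.

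Between del5 and Ctrl no single gene passed by edgeR, while DESeq2 called 144, and 10 gene lists passed. Regrouping these 6 libraries into 3 and 3 gave as many lists in 4 of 10 splits, the real one included (highest other 15). NRF2 and glutathione genes had a median of -1.17 in del5 (28 members, camera adjusted p = 1.64e-13, and adjusted p = 0.292 with an estimated correlation). MGST1 stood at 340 ± 30.5 CPM in del5 against 563 ± 65.9 in Ctrl (-0.73, SE 0.14) and the thioredoxin reductase TXNRD1 at 93.1 ± 61.8 against 326 ± 189 (-1.81, SE 0.55). Cholesterol synthesis genes had a median of -0.58 (24 members, adjusted p = 7.36e-12, and adjusted p = 0.292 with an estimated correlation). The oxidase MSMO1 stood at 103 ± 37.2 against 266.7 ± 89.7 CPM (-1.37, SE 0.30) and INSIG1, a sterol sensor, at 39.4 ± 4.84 against 86.4 ± 29.8 (-1.13, SE 0.26). These 4 genes were chosen after their values were seen. Adjusted over the list alone, 16 NRF2 genes and 7 cholesterol genes were lower, against 0 over all genes. MGST1 had an adjusted p = 0.0129 over the list alone and MSMO1 an adjusted p = 0.0191, against an adjusted p = 0.471 for both over all genes. The 16 fell to 1 without Ctrl 1, Ctrl 2, del5 2 or any 1 delT library and 0 without del5 3. The 7 became 0 without Ctrl 2, del5 2 or del5 3, 4 without delT 2 or delT 3, 16 without Ctrl 3 and 14 without del5 1. They also became 14 with the GC trend removed. Without Ctrl 1 and del5 2 together 2 NRF2 genes (list median -0.87) and 1 cholesterol gene (list median -0.35) were lower. With the identifier prefix as a term, the medians were -0.10 (adjusted p = 0.610) and -0.23 (adjusted p = 0.486), in a fit where no prefix holds both a del5 and a Ctrl library.

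Epidermal differentiation genes were higher in del5 by a median of 1.22, or 1.06 with 1 member that had 0 counts set at its bound (30 members, camera adjusted p = 0.00588, and adjusted p = 0.292 with an estimated correlation). Basal genes were higher by 0.41 (28 members, adjusted p = 0.00655, and adjusted p = 0.292 with an estimated correlation). The epidermal median was 0.67 without del5 1 and 0.33 without del5 2, and with the identifier prefix as a term it was 1.64 (adjusted p = 0.103). Targets of p53 were higher by 0.26 (34 members, adjusted p = 0.000138, and adjusted p = 0.640 with an estimated correlation), or 0.11 without Ctrl 2 and 0.08 without del5 2. Antigen presentation genes were higher by 0.38 (18 members, adjusted p = 0.00121, and adjusted p = 0.640 with an estimated correlation). Antigen presentation did not pass without Ctrl 2 (0.28, adjusted p = 0.0989) or del5 2 (0.12, adjusted p = 0.197) and was 0.59 without Ctrl 3 and 0.64 without del5 1. With the identifier prefix as a term it was 0.62 and the p53 median 0.40. Adjusted over the list alone, 1 junction gene (list adjusted p = 0.465) was higher and 1 epidermal gene lower, against 0 over all genes. They were CLDN1 (1.15, SE 0.24, adjusted p = 0.0284 over the list alone) and KRT80 (-2.01, SE 0.44, adjusted p = 0.0366 over the list alone), each with an adjusted p = 0.471 over all genes and chosen after their values were seen. In the junction list 3 genes were higher and 4 lower without del5 1, 1 was higher without del5 2 or delT 2 and 0 without any 1 of the other libraries. In the epidermal list 6 were higher without del5 2 and 1 without Ctrl 2, and 0 were lower without Ctrl 1, Ctrl 3, del5 1, del5 3 or delT 3.

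Among housekeeping lists, ribosomal protein genes were higher in del5 by a median of 0.17 (52 members, camera adjusted p = 0.000255, and adjusted p = 0.737 with an estimated correlation). Glycolysis and hypoxia genes were lower, with a median of -0.28 (36 members, adjusted p = 0.00431, and adjusted p = 0.640 with an estimated correlation). Nuclear oxidative phosphorylation genes had a median of -0.13 (46 members, adjusted p = 0.00728, and adjusted p = 0.737 with an estimated correlation). ERK-responsive genes were higher by 0.41 (30 members, adjusted p = 0.0310, and adjusted p = 0.640 with an estimated correlation). None of the members of these 4 lists passed, over all genes or over the list alone. Ribosomal genes did not pass without Ctrl 2 (0.06, adjusted p = 0.547) or del5 2 (0.03, 0.390) and stood at 0.27 without Ctrl 1 and 0.29 without del5 1. Glycolysis did not pass without Ctrl 2 (-0.17, 0.374) or del5 2 (-0.11, 0.261). Oxidative phosphorylation did not without Ctrl 1 (-0.05, 0.286) or del5 2 (-0.09, 0.494), and was -0.21 without Ctrl 3 and -0.20 without del5 1. ERK genes did not without Ctrl 1 (0.26, 0.263), Ctrl 2 (0.39, 0.201), del5 1 (0.33, 0.0900) or del5 3 (0.22, 0.105). With the identifier prefix as a term the medians of ribosomal and glycolysis genes were 0.22 (adjusted p = 0.0525) and 0.05 (0.942). Those of oxidative phosphorylation and ERK genes were -0.05 (0.414) and 0.13 (0.610, with the direction of the test reversed), and ERK genes did not pass when genes needed at least 1 CPM in 3 libraries (0.39, 0.0757). The remaining 19 lists, among them recombination (0.06, adjusted p = 0.432), replication (-0.04, 0.797), mitosis (0.04, 0.697) and interferon-stimulated genes (0.05, 0.713), had adjusted p between 0.248 and 0.999.

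By edgeR 0 of 16836 genes passed between del5 and Ctrl, with 1152 (6.84%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.142. The count was 144 with DESeq2 (59 higher and 85 lower), 0 with limma-voom, 4 with no expression filter, 9 with limma-trend on unfiltered TPM values and 4 without Ctrl 2. Replicate values did not overlap for 1461 genes (8.68%, where chance gives 10%). Of the chromosomes only 19 passed (median 0.13, adjusted p = 0.00253, and adjusted p = 0.796 with an estimated correlation), and it did not pass without Ctrl 1 or without del5 2. None of the 50 segments of chromosomes 7, 8, 13, 19 and 20 lay above 0.25. In counts simulated with a spread per gene that was the same in all groups, the same test found 21% of genes changed 2-fold and 66% of genes changed 4-fold.

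In the direct comparison of the edited groups, IL1RL1, CXCL8, CLDN1 and THBS1 were higher in del5, while PMEPA1, KRT13 and MYL9 were higher in delT. IL1RL1, the interleukin-33 receptor, stood at 92.3 ± 81.2 CPM in del5 against 0.0653 ± 0.0477 in delT (10.45, SE 1.48, adjusted p = 0.00402). CXCL8 stood at 45.5 ± 19.7 against 1.80 ± 0.704 (4.65, SE 0.48, adjusted p = 0.00103) and CLDN1 at 252 ± 90.2 against 33.1 ± 3.58 (2.93, SE 0.25, adjusted p = 0.000517). THBS1 stood at 206 ± 49.3 against 34.4 ± 5.67 (2.58, SE 0.22, adjusted p = 0.000517). PMEPA1 was lower in del5 (-2.29, SE 0.17, adjusted p = 0.000354), as were KRT13 (-6.08, SE 0.90, adjusted p = 0.00489) and MYL9 (-3.53, SE 0.50, adjusted p = 0.00390). ZNF711 and ENPP4 had 0 counts in all del5 libraries and were at least 317-fold and at least 148.3-fold lower there. NELL2 was 1902-fold lower (95% counting interval 526 to 15710), SLAIN1 1965-fold (352 to 77649) and KANK4 1640-fold (294 to 64845). The calls of the remaining 4 of the 5 largest increases in del5 ended in some fits with 1 library left out, while each kept its direction. PTGFR (at least 161-fold) ended without delT 2 (adjusted p = 0.0535) or delT 3 (0.0545) and CADM3 without delT 2 (0.0584) or delT 3 (0.0568). ACKR1 ended without del5 2, del5 3 or any 1 delT library (0.0664 to 0.0855). LTF ended without Ctrl 2, del5 2, del5 3 or any 1 delT library (0.0586 to 0.155).

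With edgeR 1974 genes passed between del5 and delT, 1073 higher and 901 lower in del5, of which 1312 changed at least 2-fold. Groups did not overlap for 6388 genes (37.9%, where chance gives 10%). The count was 1110 without del5 2, 930 without del5 3, 1289 without delT 1, 543 without delT 2 and 546 without delT 3. It was 608 with delT 2 and delT 3 summed. DESeq2 counted 3388 and limma-voom 1676, and 4755 genes had an unadjusted p under 0.05. With edgeR 0 genes passed when the identifier prefix was a term of the model, and 0 in a fit of delT 1 against del5 1 and del5 2 alone. Both fits leave few libraries to estimate the spread, so 0 does not show that the prefix accounts for the calls. With the prefix as a term all of the 87 genes chosen by rule kept their sign, with CXCL8 at 4.40, CLDN1 at 2.98 and PMEPA1 at -2.42. They were chosen in the same libraries, so their kept signs are no separate support. Of the 87 genes chosen by rule that passed, 36 passed in every fit with 1 library left out. Those named for this comparison are among them unless a library is given. Chromosomes 7, 8, 13, 19 and 20 were lower in del5, by medians of -0.49, -0.38, -0.53, -0.48 and -0.49 (camera, adjusted p from 2.35e-12 to 5.38e-08). With an estimated correlation chromosome 19 did not pass (adjusted p = 0.172).

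Antigen presentation, interferon-stimulated, NF-kB and matrix genes were 4 of the 9 lists that were higher in del5 than in delT. Antigen presentation genes had a median of 0.98 (18 members, camera adjusted p = 1.82e-05, and adjusted p = 0.501 with an estimated correlation). HLA-B (1.90, SE 0.32, adjusted p = 0.00786) and ERAP1 (1.43, SE 0.24, adjusted p = 0.00840) were among 7 members that passed (11 over the list alone), and near-identical HLA genes may share reads. Interferon-stimulated genes had 0.79 (41 members, adjusted p = 0.000141, and adjusted p = 0.501 with an estimated correlation). The antiviral synthetase OAS2 (3.66, SE 0.64, adjusted p = 0.00919) was among 9 higher and 1 lower (15 and 2 over the list alone). NF-kB targets had 1.55, or 0.74 without del5 2 (28 members, adjusted p = 0.000793, and adjusted p = 0.497 with an estimated correlation), with 10 higher (13 and 1 lower over the list alone). Matrix genes had 0.49 (35 members, adjusted p = 0.00706, and adjusted p = 0.259 with an estimated correlation). The TGF-beta binding protein LTBP1 (1.71, SE 0.26, adjusted p = 0.00562) was among 12 higher (12 and 3 lower over the list alone). YAP/TAZ targets had 0.41 (22 members, adjusted p = 0.0195, and adjusted p = 0.259 with an estimated correlation). CCN2 (3.02, SE 0.49, adjusted p = 0.00708) was among 6 higher (6 and 2 lower over the list alone). The YAP/TAZ list did not pass with the identifier prefix as a term (0.57, adjusted p = 0.0640). In delT 1 against del5 1 and del5 2 alone, which share a prefix, matrix genes were at 0.62 (adjusted p = 0.0502) and YAP/TAZ targets at 0.55 (adjusted p = 0.0856). The 1 lower interferon gene, EPSTI1 (-2.19, adjusted p = 0.0418, chosen after its values were seen), lies on chromosome 13 and ended without Ctrl 2, del5 2, del5 3 or any 1 delT library (0.0586 to 0.132).

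Single libraries moved these counts. Antigen presentation counted 4 higher genes without del5 2, del5 3 or delT 1 and 3 without delT 2 or delT 3. Interferon-stimulated genes counted 6 without del5 2 or del5 3, 4 without delT 2 and 5 without delT 3, with 0 lower ones without Ctrl 2, del5 2, del5 3 or any 1 delT library. NF-kB targets counted 6 without delT 2 and 5 without delT 3, and matrix genes 7 without delT 2 or delT 3. YAP/TAZ targets counted 2 without del5 2 or del5 3 and 1 without any 1 delT library, with 1 lower without Ctrl 1 or del5 1. Lower matrix genes numbered 2 without Ctrl 2 or Ctrl 3 and 1 without del5 1 or delT 1.

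Targets of p53 were also higher in del5 than in delT (median 0.44, 34 members, camera adjusted p = 0.00611, and adjusted p = 0.661 with an estimated correlation). So were basal genes (0.43, 28 members, adjusted p = 0.0195, and adjusted p = 0.259 with an estimated correlation). Stromal markers were higher (1.34, 10 members, adjusted p = 0.00611, and adjusted p = 0.275 with an estimated correlation), as were histones (1.74, 12 members, adjusted p = 0.0171, and adjusted p = 0.742 with an estimated correlation). The stress sensor SESN1 (1.11, SE 0.18, adjusted p = 0.00667) and PLK2 (1.26, SE 0.21, adjusted p = 0.00786) were among 5 higher p53 targets (9 over the list alone). DCN (6.52, SE 1.052, adjusted p = 0.00686) and TEK (4.40, SE 0.54, adjusted p = 0.00206) were among 5 higher stromal markers (5 over the list alone). Of basal genes 4 were higher, also over the list alone, and of histones 1. The p53 list did not pass without del5 2 (0.34, adjusted p = 0.0597), basal genes without delT 1 (0.40, 0.0508), and histones without del5 2 (0.78, 0.0597) or delT 1 (1.60, 0.0673). Stromal markers did not pass without delT 1 (0.53, 0.0907) and moved to 0.58 without Ctrl 2, 0.61 without Ctrl 3, 0.58 without del5 1, 0.16 without del5 2 and 0.60 without delT 2. With no expression filter they were at 0.01 (0.335). Of p53 targets 1 was lower without Ctrl 1 or delT 1, and 2 histones were higher without Ctrl 3. The higher p53 targets numbered 3 without delT 1 and 2 without delT 2 or delT 3. For basal genes the count was 1 without del5 2, 2 without del5 3 and 0 without any 1 delT library. It was 3 without delT 2 for stromal markers, and 0 without del5 2, del5 3 or any 1 delT library for histones.

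Recombination genes were lower in del5 than in delT (median -0.28, 44 members, camera adjusted p = 0.00706, and adjusted p = 0.742 with an estimated correlation). So were replication genes (-0.28, 50 members, adjusted p = 0.00300, and adjusted p = 0.742 with an estimated correlation) and mitosis genes (-0.42, 49 members, adjusted p = 8.56e-05, and adjusted p = 0.742 with an estimated correlation). Without del5 2 none of the 3 passed (-0.10, adjusted p = 0.235, -0.01, 0.508 and -0.11, 0.0597). Without del5 1 the medians were -0.45, -0.45 and -0.68, and that of replication was -0.45 without del5 3. Of recombination genes 3 were lower and 1 higher (2 and 1 over the list alone), and 1 replication gene and 2 mitosis genes were lower (0 over the list alone). Recombination counted 2 lower without Ctrl 3, del5 2 or delT 1, 1 without del5 3 or delT 2 and 0 without delT 3, and 0 higher without del5 2, del5 3 or any 1 delT library. Replication counted 3 without Ctrl 1, 2 without Ctrl 2 or del5 1 and 0 without del5 2, del5 3 or any 1 delT library. Mitosis counted 4 without del5 1, 1 without Ctrl 2, del5 3 or delT 1 and 0 without delT 2 or delT 3. The remaining 17 lists had adjusted p between 0.0866 and 0.819, including R-loop (-0.13), NRF2 (0.16) and cholesterol genes (-0.10). Of their members, 7 mesenchymal genes were higher and 2 lower (11 and 3 over the list alone), 3 and 4 junction genes (4 and 5) and 4 and 0 luminal genes (5 and 1). The counts were likewise 3 and 6 for epidermal genes (6 and 10), 5 and 0 for NRF2 genes (6 and 0), 2 and 4 for TGF-beta targets (2 and 4), 3 and 1 for ERK-responsive genes (3 and 1) and 0 and 3 for R-loop genes (0 and 3). Without delT 2 these were 2 and 2, 2 and 2, 0 and 0, 0 and 1, 2 and 0, 1 and 1, 1 and 0, and 0 and 0.

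No gene passed against Ctrl in both edited groups by edgeR, since none passed in del5. With other settings the count in the same direction was 50 with DESeq2, 3 with no expression filter, 6 with unfiltered TPM values and 4 without Ctrl 2. Changes against Ctrl correlated across genes with r = 0.149 (genes are not independent replicates). In 10 simulations of unchanged groups that share their controls the mean was 0.485. The 2 values are not alike, since changes in delT alone lower r and the simulated groups hold none. The observed covariance was 0.127, against a mean of 0.114 and a highest of 0.118 simulated. The simulation gave all groups the same spread, while Ctrl had the largest, so neither value decides whether changes are shared. The delT group differed from both other groups in 1449 genes, 665 higher in delT, such as SLAIN1 and PMEPA1, and 784 lower, such as CXCL8 and THBS1. Independent lists would share 50.3 and 72.5, but both lists rest on the same 3 delT libraries, so part of the overlap may come from these. Simulated unchanged groups gave 0 and set no level to compare with. The number was 1000 without del5 2, 784 without del5 3, 872 without delT 1, 407 without delT 2 and 424 without delT 3. It was 464 with delT 2 and delT 3 summed, and 890 with chromosome medians removed (241 higher and 649 lower in delT).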

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

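The change against Ctrl differed between the 2 edited groups for 1974 genes, and for chromosomes 7, 8, 13, 19 and 20 by medians of -0.49, -0.38, -0.53, -0.48 and -0.49 (del5 minus delT). These results are listed because the test of the difference between the edited groups itself passed. Chromosome 19 did not pass with an estimated correlation (adjusted p = 0.172), and 0 genes did with the identifier prefix as a term. That term leaves few libraries to estimate the spread, so 0 does not show that the prefix accounts for the calls. With that term all 87 named genes kept their sign (CXCL8 4.40 against 4.65, PMEPA1 -2.42 against -2.29). They were chosen in these same libraries, so this is no separate support. Of the tests below, the fit of delT 2 and 3 against Ctrl 3 was chosen after the chromosome result was seen and the reading of a direct dosage effect after the counts were seen. The per-library folds were likewise set against 1.5 after they were seen, and the other tests were written down before their result.

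A trend on GC content does not account for the first pattern, the higher level of 5 whole chromosomes in delT, since the lowest of the 5 medians was still 0.33 after that trend was removed, and neither does the identifier prefix, since within the prefix shared by Ctrl 3, delT 2 and delT 3 the lowest was 0.36. An extra copy of each chromosome predicts a rise along its whole length, and 47 of 50 segments of genes in order lay above 0.25. The folds of the 5 chromosomes pooled were 1.48, 1.54 and 1.53 per library, near the 1.5 of 3 copies in place of 2, but single chromosomes ranged from a log2 median of 0.35 (chromosome 8, delT 3) to 0.75 (chromosome 19, delT 2) over the Ctrl mean, with other chromosomes at -0.09 to -0.07. The 47 segments are consistent with extra copies in the delT cells, although the sizes differ between chromosomes and RNA does not count DNA copies. Whether such copies came with the mutation, with cloning or with time in culture could not be tested, because delT cells carry all of these together.

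The second pattern is the number of genes that passed between delT and Ctrl. Direct dosage of extra chromosome copies is argued against as the whole cause, since 1341 genes passed with chromosome medians removed, while indirect effects of such copies on other genes would survive that removal and stay open. The identifier prefix is argued against as the whole cause, since of the 500 genes with the smallest p between delT 1 and Ctrl 1 and 2, 97.6% had the same sign in delT 2 and 3 against Ctrl 3 (96.9% of 391 on other chromosomes, and 75.3% of all genes). The real grouping gave 2077 genes and the highest of the other splits 0, so that 1 of 10 splits gave as many, too few for a share under 0.05. An effect of the mutation and of the founding cell of a clone also remain open, since the labels do not say how many clones the delT libraries hold.

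The third pattern is that edgeR called 0 genes between del5 and Ctrl, as did limma-voom, while DESeq2 called 144. For edgeR, spread between libraries of a group may have hidden 2-fold changes, since 21% of them passed in simulated counts. It would hide fewer 4-fold changes, of which 66% passed there. The simulation gave all groups the same spread, while the real one was 40.1% in Ctrl, 35.5% in del5 and 21.2% in delT. The real shares may therefore differ. A GC trend does not account for the count of 0, as 0 genes passed after it was removed. The most that passed without 1 of the 6 libraries was 4, fewer than predicted if 1 library standing apart were the cause. Leaving a library out also weakens the test, so this does not exclude that cause. Other splits decide nothing here, since 10 of 10 give at least as many as a real count of 0 by construction (highest other 1). A small effect of del5 was not excluded.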

How the results depend on the processing

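Between del5 and Ctrl the 0 genes became 4 with no filter, 144 with DESeq2, 9 with unfiltered TPM and 1 without Ctrl 1 and del5 2 together, and 0 to 4 with 1 library left out. BRCA2 ranged from -0.27 to 0.19 with 1 library left out, was 0.27 without Ctrl 1 and del5 2 and was -0.61 with the prefix term. The 10 lists became 0 with an estimated correlation, 4 with the prefix term and 7 to 12 with 1 library left out. With the prefix term 2 lists reversed in the direction of the test, ERK genes (median 0.13) among them. The glycolysis median changed sign with that term (0.0466). Oxidative phosphorylation (0.0210) reversed without Ctrl 1 and del5 2. The 1 chromosome became 0 with an estimated correlation, with the GC trend removed and without Ctrl 1 and del5 2, and 0 to 1 with 1 library left out. Except where fewer libraries were fitted, the cause was not tested, here and below.

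Between delT and Ctrl the 2077 genes became 3394 with DESeq2, 46 with the prefix term, 1175 with unfiltered TPM, 1341 with chromosome medians removed, 742 with delT 2 and 3 summed, 8706 within the prefix of Ctrl 3, delT 2 and delT 3, where the spread of the closest pair makes p-values too small, and 641 to 2441 with 1 library left out. BRCA2 passed with DESeq2 (0.81), 2 groups alone (0.80) and without Ctrl 1 and del5 2 (0.89), was 0.61 within that prefix, where its p is no evidence for the same reason, and ranged from 0.68 to 0.91 with 1 library left out. The 13 lists became 0 with an estimated correlation and 9 to 13 with 1 library left out. The 10 chromosomes became 5 with an estimated correlation (chromosome 19 at 0.62, adjusted p = 0.0942), with no filter, with the prefix term, within the prefix and without Ctrl 1 and del5 2, 6 with delT 2 and 3 summed, and 6 to 10 with 1 library left out.

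Between del5 and delT the 1974 genes became 3388 with DESeq2, 0 with the prefix term and within the prefix of del5 1, del5 2 and delT 1, 1000 with unfiltered TPM, 1274 with chromosome medians removed, 608 with delT 2 and 3 summed, 1312 at 2-fold, and 543 to 2453 with 1 library left out. BRCA2 passed with DESeq2 (-0.89) and the replicate block (-0.94), ranged from -1.08 to -0.62 with 1 library left out and was -1.24 with the prefix term. The 12 lists became 0 with an estimated correlation and 9 to 15 with 1 library left out, and chromosome 19 (-0.48) did not pass with an estimated correlation (adjusted p = 0.172). The 0 genes that passed in both edited groups became 3 with no filter, 50 with DESeq2, 6 with unfiltered TPM and 0 to 4 with 1 library left out.

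Replicate numbers do not pair the libraries: 4 of 9 same-number pairs correlated over 0.1, and 3 libraries correlated best with their own number in both other groups. With that block 0, 2294 and 2075 genes, 10, 12 and 12 lists and 1, 11 and 5 chromosomes passed in del5 with Ctrl, delT with Ctrl and del5 with delT. Other alternatives kept the numbers of genes, lists and chromosomes that passed in each comparison within 1.5 times. Depth of 43132100 to 91499600 counts limits genes near the floor of 0.0328 to 0.0696 CPM.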

Other observations

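Scores of 2 gene lists separated the 3 Ctrl libraries from all 6 edited ones: epidermal differentiation genes were higher in the edited libraries (Ctrl minus edited -1.13) and cholesterol synthesis genes lower (0.54), each with an exact permutation p of 0.0238 and an adjusted p of 0.345 over 29 lists. The 3 delT libraries were separated from the other 6 by 14 lists (adjusted p = 0.0493 each, from the smallest possible permutation p, 0.0238). Of these 3 were higher in delT (recombination 0.40, TGF-beta targets 0.36 and R-loop genes 0.25). TGF-beta targets did not pass between delT and Ctrl (camera adjusted p = 0.226) or between del5 and delT (0.277). R-loop genes did not pass between del5 and delT (camera adjusted p = 0.0866). The other 11 were lower, such as stromal markers (-1.62), NF-kB targets (-1.29) and NRF2 genes (-1.21), although NRF2 genes did not pass between del5 and delT (camera adjusted p = 0.0933). Neither grouping of 3 against 6 was among the comparisons fixed beforehand. The permutation also takes delT 2 and delT 3, the closest pair, as separate libraries, so these p-values may be too small.

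A hypothesis formed after the list results were seen was that NRF2 genes stand higher in unedited than in edited cells of either mutation. The mean list score of Ctrl exceeded that of the edited libraries by 1.41 (exact permutation p = 0.0476, 84 splits), but Ctrl 3 (0.22) lay below del5 1 (0.48), and the hypothesis came from these same scores, so the test decides nothing either way.

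Regrouping 6 libraries into 3 and 3 gave as many lists as the real grouping in 4 of 10 splits of del5 with Ctrl (10 lists, highest other 15), 1 of 10 of delT with Ctrl (13, highest other 12) and 4 of 10 of del5 with delT (12, highest other 13). It gave as many chromosomes in 9 of 10 (1, highest other 7), 2 of 10 (10, highest other 10) and 8 of 10 splits (5, highest other 7), and as many genes in 1 of 10 splits of del5 with delT (1974, highest other 1). These splits are too few for a share under 0.05. For del5 with Ctrl, mixed groupings gave up to 15 lists and 7 chromosomes. The numbers of lists and chromosomes therefore do not set that real grouping apart from mixed ones. In the comparisons with delT, every regrouping also leaves more delT libraries on one side than on the other. A difference carried by all delT libraries then stays in part, so these splits do not show what arises without one. The split of Ctrl 1, del5 1 and del5 2 from Ctrl 2, Ctrl 3 and del5 3 gave 7 chromosomes against 1 for the real grouping, both with the preset correlation.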
